A study of Mus musculus with 39 samples.

How the data were processed

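RNA was sequenced from single mouse cells. Per the labels, the starting cells were spinal cord astrocytes of young mice, purified with magnetic beads (MACS), and the genes introduced into them in culture were Ascl1 and Neurog2, a pair of proneural transcription factors. Whether a cell received 1 or both was not stated, and libraries were grouped by the factor in the label. The labels write Neurog2 as Ngn2. Culture lasted 3 to 4 weeks in a medium that held 2% B27 supplement, and growth factors (BDNF, GDNF, NT-3), cAMP and N2 were added at intervals of 3 days. Each cell was taken up by suction and amplified with the SmartSeq2 protocol. The series title names the method Patch-seq, in which a cell is recorded electrically before its RNA is collected. Recordings were not used here.

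The 39 libraries carried 3 labels: 6 were Ascl1 astrocytes, 18 were Ascl1 neurons and 15 were Ngn2 neurons. The 39 columns of the table each matched a sample by the library number in its title, and 0 columns matched no sample. A pair of libraries shared the title number 5 among the Ascl1 astrocytes. Their Pearson correlation over genes was 0.603, within the 0.462 to 0.612 of all 15 pairs of Ascl1 astrocyte libraries, and they were kept as separate cells. The library numbers fell into 2 runs, 9860 to 9891 and 9898 to 9904. The second run held only the 7 libraries labelled Ascl1 neuron 12 to 18.

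The values deposited by the authors are a signal, normalised reads per gene and library. The deposited notes name the aligner STAR 2.6.0a, the quantifier RSEM 1.3.0 and the mouse genome build GRCm38, and do not say how the normalisation was made. In every library at least 99.97% of the values above 0 were whole multiples of 1 smallest step, within a tolerance of 0.01 of a step. Each value was therefore a read count divided by 1 factor per library, and dividing by the step gave back the reads. Recovered reads ran from 614990 to 2991938 per library, with a median of 1395001. Values printed here are the deposited normalised reads unless reads are named.

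The table held 32241 Ensembl gene IDs. A lookup of GRCm38 gene names matched 32185 of them, and the other 56 kept their ID as name. IDs that shared a symbol were summed, which gave 32227 gene names, 31986 of them above 0 in at least 1 library. Coordinates came from the GENCODE M21 annotation of GRCm38. The reads of an introduced factor and of the cell's own gene were not separated in the table.

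The 3 comparisons were Ascl1 neurons against Ascl1 astrocytes, Ngn2 neurons against Ascl1 astrocytes, and Ngn2 neurons against Ascl1 neurons. The labels named no animal or culture, so cells of a group were not replicates and each group counted as 1 sample. For this reason no test between groups was run on the values or on the recovered reads, and no p-value, standard error or count of changed genes was made. For each gene the group mean of log2(value + 1) was taken over cells, and the log2 difference between the groups is given with the means and standard deviations (SD) over cells. The SD describes the cells measured, not animals or cultures. Shares of libraries carry exact (Clopper-Pearson) 95% intervals. Where a share was 0, the limit given is that of 3 libraries of the total. Intervals and limits cover counting error only.

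The rule for named genes, the gene lists and the way lists were compared were fixed before the data were examined. Genes to name were, in each comparison, the 12 with the highest and the 12 with the lowest log2 difference. They were taken from the 5000 genes with the highest average of the 3 group means. They had to be above 0 in at least 50% of the libraries of the higher group and to keep their sign when any 1 library was left out. Predicted genes, RIKEN clones, pseudogenes, ribosomal protein genes and genes of the mitochondrial genome were not named by this rule. Ascl1, Neurog2, 9 transmitter genes and the 4 members of each gene list with the largest differences were named in addition.

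There were 36 gene lists with 583 genes, of which 17 were not in the table. Cell identity was covered by lists for astrocytes, reactive or immature glia, pan-neuronal genes, inhibitory, excitatory, cholinergic or motor and monoaminergic identity, neuropeptides and ventral interneuron factors. Neuronal function was covered by lists for presynaptic release, postsynaptic scaffolds, glial potassium and gap junction channels, receptors for glutamate and for GABA and glycine, and voltage-gated sodium, potassium and calcium channels. Programmes were covered by Hox genes, forebrain and midbrain factors, genes associated with Ascl1 and with Neurog2, neuronal transcription factors, and the cell cycle. Cell state was covered by immediate early genes, heat shock, oxidative stress, mitochondrially encoded genes, glycolysis, oxidative phosphorylation and cholesterol synthesis. Other cell types were covered by lists for the oligodendrocyte lineage, microglia, endothelium, mural cells and fibroblasts, ependyma and Schwann cells.

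The value of a list was the median log2 difference over its members above 0 in at least 1 library. It was placed among 10000 random lists of as many genes matched on expression in 20 bins. A list is called apart when it lay outside the central 95% of these random lists. This describes the libraries measured and is not a test between groups. The score of a list in a library was the mean of log2(value + 1) over its members.

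The procedure was tested on simulated data with 200 changed genes in each comparison. Median changes of 1, 2 and 3 on the log2 scale were recovered as 0.94, 1.93 and 2.86 in the first comparison, 1.06, 1.88 and 2.83 in the second, and 0.89, 1.84 and 2.67 in the third. Of the 24 genes named by size, 17, 16 and 21 were changed genes. Of 1000 unchanged lists of 20 simulated genes, 5.9%, 5.7% and 4.3% were called apart. These rates describe the simulated lists only. The gene lists used here differ in size, and their members can vary together or be detected in few libraries. How often such lists are called apart without a change was not tested.

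Each result was recomputed with pseudocounts of 0.1 and 10 in place of 1, with each library rescaled to the same total, with linear group means, with medians over cells, and with only libraries of at least 2000 genes above 0. It was also recomputed with the pair titled 5 averaged, with list members above 0 in at least 3 libraries, with the largest value for a shared symbol, with other thresholds and gene filters, and with each library left out in turn. Alternatives chosen after seeing the data left out Ngn2 neuron 7 or the 7 libraries Ascl1 neuron 12 to 18, thinned each library to 600000 reads, or scaled the recovered reads by their upper quartile. Thinning was run for genes detected and shares of libraries, not for gene differences or lists. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the figures used matplotlib 3.10.9.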

Results

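The data were single-cell RNA sequencing libraries of cells from cultures of mouse spinal cord astrocytes. The series names Ascl1 and Neurog2 as the introduced factors, the labels name 1 factor per cell, and neither says whether a cell received 1 or both. There were 39 libraries of 1 cell each: 6 labelled Ascl1 astrocyte, 18 labelled Ascl1 neuron and 15 labelled Ngn2 neuron. The labels named no animal or culture, so there were no replicates above the cell, and every SD below is over cells. Differences are of mean log2(normalised reads + 1), called log2 differences, and carry no test between groups. Recovered reads per library ran from 672234 to 2196469 in the astrocytes, from 1099058 to 2238742 in the Ascl1 neurons and from 614990 to 2991938 in the Ngn2 neurons. The median number of genes above 0 was 7411.5 in the astrocytes (range 6061 to 12207), 8359 in the Ascl1 neurons (7284 to 10024) and 8372 in the Ngn2 neurons (6290 to 25472). Ngn2 neuron 7 held the 25472 genes, and the other 14 Ngn2 neurons held at most 10544. Transcripts of the mitochondrial genome made up 3.03% ± 2.67 (SD, n = 6) of the values in the astrocytes, 3.40% ± 2.42 (SD, n = 18) in the Ascl1 neurons and 2.72% ± 2.56 (SD, n = 15) in the Ngn2 neurons. In the libraries labelled Ascl1 neuron 12 to 18 this share was 5.42% ± 1.91 (SD, n = 7), against 2.12% ± 1.76 (SD, n = 11) in numbers 1 to 11.

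**Figure D1:**
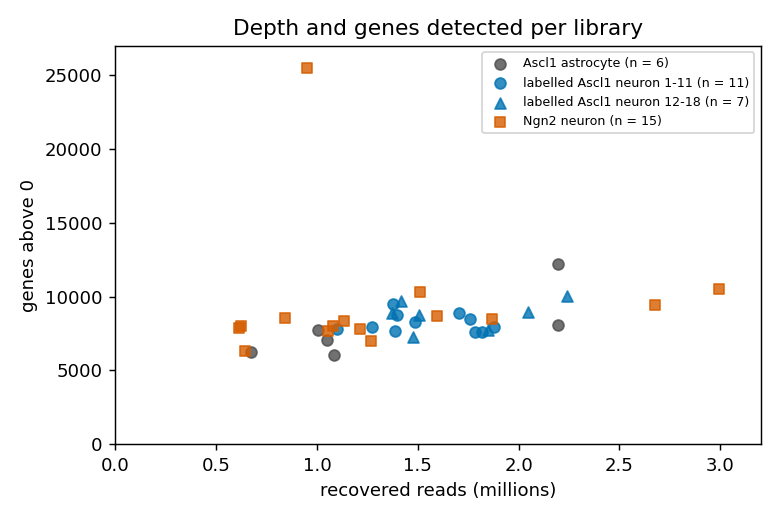
Genes above 0 against recovered reads in each of the 39 libraries, 1 point per library, coloured by label. Ngn2 neuron 7 held 25472 genes and every other library at most 12207.

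Ascl1 and Neurog2 were read first, as a check of the labels. Ascl1 (ENSMUSG00000020052, chromosome 10, 87490819 to 87493660, minus strand, GRCm38) had a mean of 441 ± 471 normalised reads (SD, n = 18) in the Ascl1 neurons, 118 ± 185 (SD, n = 6) in the Ascl1 astrocytes (54.1 without number 1) and 1.81 ± 1.89 (SD, n = 15) in the Ngn2 neurons. The astrocytes had a median of 9.46, and 3 of the 6 lay within the range of the Ngn2 neurons (0 to 6.91). Neurog2 (ENSMUSG00000027967, chromosome 3, 127633135 to 127635631, plus strand) had a mean of 304 ± 292 (SD, n = 15) in the Ngn2 neurons and 1.40 ± 0.843 (SD, n = 6) in the Ascl1 astrocytes. In the libraries labelled Ascl1 neuron 1 to 11, Ascl1 stood at 698 ± 434 (SD, n = 11) and Neurog2 at 0.318 ± 0.477. In the libraries labelled Ascl1 neuron 12 to 18, Ascl1 stood at 35.8 ± 41.6 (SD, n = 7; 22.0 without number 16) and Neurog2 at 213 ± 145, with all 7 of them between 82.4 and 493. These 7 libraries carry the second run of library numbers, which holds no other group, so run and label cannot be told apart.

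The log2 difference in Ascl1 was 3.15 between Ascl1 neurons and Ascl1 astrocytes, 5.13 without Ascl1 neuron 12 to 18. It was -2.81 between Ngn2 neurons and Ascl1 astrocytes (-1.86 without Ascl1 astrocyte 1) and -5.97 between Ngn2 and Ascl1 neurons (-7.95 without Ascl1 neuron 12 to 18). For Neurog2 the differences were 1.95, 6.32 and 4.38 in the same order. Without Ascl1 neuron 12 to 18 the first of these turned to -0.84 and the last was 7.16.

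**Figure D2:**
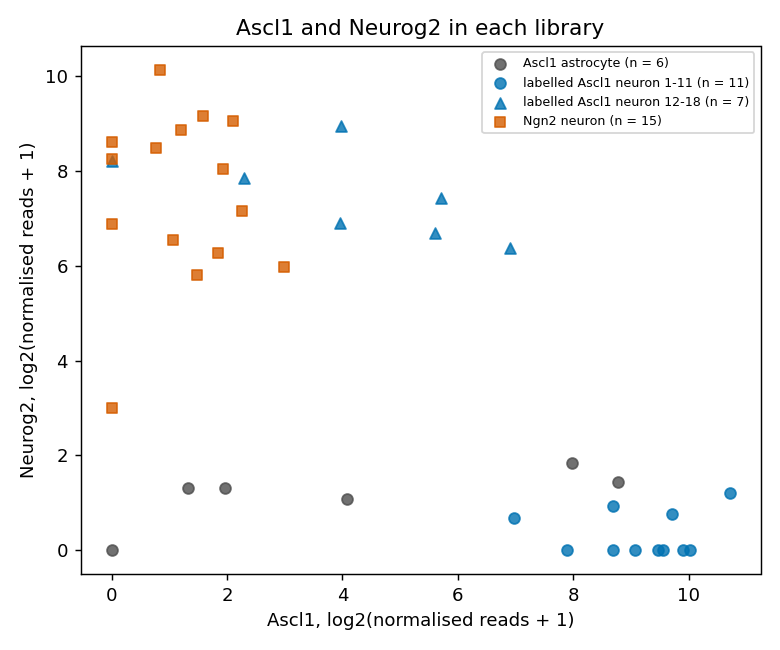
Neurog2 against Ascl1 in each library, both as log2(normalised reads + 1), coloured by label, with triangles for the libraries labelled Ascl1 neuron 12 to 18. The 7 triangles lie at Neurog2 values of 82.4 to 493 normalised reads, where libraries labelled Ascl1 neuron 1 to 11 do not exceed 1.33.

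The comparison of Ascl1 neurons with Ascl1 astrocytes set 2 fate labels under 1 factor label against each other. The cells did not all hold that factor alike, since Ascl1 was low in 3 of 6 astrocytes and Neurog2 was high in 7 of 18 neurons. Syp, which encodes the synaptic vesicle protein synaptophysin (ENSMUSG00000031144, chromosome X, 7638471 to 7653256), stood at 541 ± 380 normalised reads (SD, n = 18) against 3.68 ± 1.45 (SD, n = 6), a log2 difference of 6.55. Stmn3, a stathmin that binds tubulin, stood at 704 ± 255 against 7.54 ± 5.83, and Tmem59l at 367 ± 231 against 1.63 ± 1.66. On the lower side, Aldh1l1, a folate enzyme used as an astrocyte marker (ENSMUSG00000030088, chromosome 6, 90486427 to 90600203), stood at 46.0 ± 79.1 against 1746 ± 659. Gfap, the glial intermediate filament (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), stood at 820 ± 1864 (432 without Ascl1 neuron 12) against 16730 ± 13177. Their log2 differences were -8.03 and -7.37, and -10.08 and -9.66 without Ascl1 neuron 12 to 18. Aldh1l1 stood at 0.619 ± 0.566 in Ascl1 neuron 1 to 11 and 117 ± 89.7 in numbers 12 to 18, and Gfap at 54.9 ± 107 (25.1 without number 3) and 2023 ± 2658 (1124 without number 12).

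The other genes named by size on the higher side were Bex2 (6.38), Sept3 (6.32), Ap3b2 (6.29), Ptprn (6.18), Prkar1b (6.03), Pnmal2, Clstn3 (5.93), Chga (5.91) and Resp18 (5.88). On the lower side they were the nuclear noncoding RNA Neat1 (-8.64), Sdc4 (-8.57), Sparc (-7.67), Ndrg1 (-7.52), Fstl1 (-7.33), Irak2 (-7.30), Hepacam, Igfbpl1 (-7.27), Ppp1r3c (-7.23) and Dbx2.

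Of the 36 gene lists, 11 lay apart from expression-matched random lists. The astrocyte list had a median log2 difference of -5.20, with 24 of 26 members lower, among them Atp1b2 (-7.08) and Aldoc (-6.79), and its score was 4.08 ± 2.11 (SD, n = 18) against 8.40 ± 0.716 (SD, n = 6). The list of reactive or immature glia had a median of -1.51, with 13 of 21 members lower, among them the intermediate filament Vim (-6.12). The pan-neuronal list had a median of 2.91, with 23 of 26 members higher, among them Celf4 (5.68) and Ina (5.43), and presynaptic release had a median of 2.85, with 25 of 26 higher, among them Cplx1 (5.79), Snap25 (5.65) and Syn1 (5.65). Voltage-gated sodium channels had a median of 2.19, with 8 of 9 members higher, led by the subunits Scn1b (4.20) and Scn2b (4.18). In the libraries labelled Ascl1 neuron 12 to 18 the astrocyte score lay between 5.07 and 7.93, against 1.85 to 3.72 in numbers 1 to 11, and without these 7 libraries the astrocyte list had a median of -6.98 and the pan-neuronal list 3.50.

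Cholesterol synthesis had a median of 1.69, with 17 of 19 members higher, among them Mvd (3.81), a mevalonate pathway enzyme, and Msmo1 (3.43), a sterol oxidase. Neuropeptides had a median of 0.42, with 8 of 12 members higher, led by galanin, Gal (3.80), and the enkephalin precursor Penk (2.70). Both differences are larger without Ascl1 neuron 12 to 18. Between Ngn2 and Ascl1 neurons leaving these out took Gal from -3.04 to -5.05 and Penk from -2.37 to -4.03. The genes associated with Ascl1 had a median of 0.72, with 10 of 16 higher, led by the Notch ligand Dll3 (5.40) and by Hes6 (4.11). Igfbpl1, named above among the lower genes, is also a member and lay further from 0 in the other direction. Voltage-gated calcium channels had a median of 0.64, with 13 of 16 higher, led by Cacng2 (3.24), a subunit that also serves AMPA receptors. Cholinergic or motor identity had a median of 0.37, with 5 of 9 members higher and 0 lower, led by Lhx3 (2.84), which was above 0 in 10 of 11 libraries of Ascl1 neuron 1 to 11 and in 1 of 7 of numbers 12 to 18. Lhx3 is also a member of the list of ventral interneuron factors, and Chat, Mnx1, Lhx4 and Phox2b were at 0 in both groups. Schwann cell genes had a median of 0.23, with 5 of 9 members higher, led by the neurotrophin receptor Ngfr (1.99). The difference of Ngfr is larger without Ascl1 neuron 12 to 18, which took it from -2.34 to -3.94 between Ngn2 and Ascl1 neurons.

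Without Ascl1 neuron 12 to 18 the cholinergic or motor list and the Schwann list both had a median of 0.00 and were no longer apart, and the calcium channels had 1.04. The cholinergic or motor list was also ended by leaving out Ascl1 neuron 2 or 8 (0.00 each) and, at a value of 0.58, by leaving out Ngn2 neuron 7. Without that library the members Chat, Mnx1, Lhx4 and Phox2b were at 0 everywhere and no longer counted. The Schwann list was ended by leaving out Ascl1 neuron 13 or 16 (0.00 each) while it stood at 0.45 without Ngn2 neuron 7. The calcium channels were ended by leaving out Ascl1 astrocyte 1 (0.55), Ascl1 astrocyte 5 of library 9864 (0.59), Ascl1 neuron 5 (0.51) or Ascl1 neuron 10 (0.41). The genes associated with Ascl1 were ended by leaving out Ascl1 astrocyte 3 (0.70), Ascl1 astrocyte 5 of library 9864 (0.70), Ascl1 neuron 2 (0.53), 8 (0.51) or 10 (0.58), and had 1.21 without Ascl1 neuron 3. With medians over cells, 5 of the 11 lists stayed apart: astrocyte, reactive glia, pan-neuronal, presynaptic release and cholesterol synthesis. The genes associated with Ascl1 were also ended by each other pseudocount and each rescaling, the calcium channels by a pseudocount of 0.1, the Schwann list by linear means, and the Schwann and cholinergic or motor lists by the limit to members above 0 in at least 3 libraries.

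The comparison of Ngn2 neurons with Ascl1 astrocytes differed in factor and in fate label together. Cbln4, a secreted synapse organiser of the cerebellin family (ENSMUSG00000067578, chromosome 2, 172036233 to 172043466), stood at 714 ± 512 normalised reads (SD, n = 15) against 2.52 ± 2.82 (SD, n = 6), a log2 difference of 7.37. Syp stood at 779 ± 300 against 3.68 ± 1.45 (7.32), and Stmn3 at 975 ± 428 against 7.54 ± 5.83 (6.96). Aldh1l1 stood at 5.32 ± 14.1 (1.72 without Ngn2 neuron 8) against 1746 ± 659 (-9.31). Gfap stood at 68.8 ± 120 (40.6 without Ngn2 neuron 8) against 16730 ± 13177 (-8.58). Vim stood at 184 ± 323 (115 without Ngn2 neuron 1) against 17455 ± 4686 (-8.47).

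The other genes named by size on the higher side were Plcxd3 (7.22), Sult4a1 (7.21), Pnmal2 (7.14), the sialyltransferase St8sia5 (7.05), Fxyd6 (6.72), the noncoding RNA Snhg11 (6.72), Clstn3 (6.70), Sept3 (6.63) and Vat1l (6.60). On the lower side they were the extracellular superoxide dismutase Sod3, the endothelin receptor Ednrb (-8.42), Aldoc (-8.30), Neat1 (-8.29), Ndrg1 (-8.22), Sdc4 (-8.05), Zfp36l1 (-8.03), Sfxn5 (-7.98) and Sparc (-7.89).

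Again 11 lists lay apart. The counts of higher members below include Ngn2 neuron 7, where a few reads can raise a member not detected elsewhere. Among genes matched on expression to the lists with more members higher, 53.5% to 57.8% were higher. These shares include that library as well, and the counts are not given without it. The astrocyte list had a median of -5.74, with 25 of 26 members lower, among them the glutamate transporter Slc1a3 (-7.54), and its score was 3.55 ± 0.974 (SD, n = 15) against 8.40 ± 0.716 (SD, n = 6). Reactive or immature glia had 14 of 21 members lower, among them Fabp7 (-7.46) and Cd9 (-6.85), and a score of 2.30 ± 0.818 against 4.85 ± 0.865; its median was -2.34, or -0.89 without Ascl1 astrocyte 3. The pan-neuronal list had a median of 3.46, with 22 of 26 higher, among them Mapt (5.16) and Tubb3 (4.94). Presynaptic release had a median of 4.20, with 25 of 26 higher, among them Snap25 (6.57), Rab3c (6.48) and Cplx1 (6.47). Postsynaptic scaffolds had a median of 1.60, with 16 of 20 higher, led by the kinase subunit Camk2b (5.68). Among channels and receptors, all 9 sodium channel genes were higher (median 2.19; Scn2b 5.56, Scn8a 5.16), as were 20 of 22 potassium channel genes (median 0.95; Kcnq2 5.33), 15 of 16 calcium channel genes (median 0.83; Cacna1b 3.97) and 12 of 15 glutamate receptor genes (median 1.85; Grin1 6.04, Gria2 5.74). The genes associated with Neurog2 had a median of 0.96, with 13 of 16 higher, led by Trnp1 (4.01), and neuronal transcription factors a median of 0.84, with 15 of 22 higher, led by Myt1 (3.92) and Myt1l (3.65).

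The calcium channels were ended by leaving out any 1 of 10 libraries (medians 0.56 to 0.77): Ascl1 astrocyte 1, either Ascl1 astrocyte 5, or Ngn2 neuron 2, 6, 7, 9, 11, 13 or 15. The neuronal transcription factors were ended by leaving out any 1 of 12 (0.33 to 0.79): Ascl1 astrocyte 2, 3 or 4, either Ascl1 astrocyte 5, or Ngn2 neuron 8, 9, 11, 12, 13, 14 or 15. With medians over cells 7 of the 11 stayed apart, without the sodium, potassium and calcium channels and the genes associated with Neurog2, and with linear means 8, without the potassium and calcium channels and the neuronal transcription factors. The calcium channels were also ended by a pseudocount of 0.1 and by leaving Ascl1 neuron 12 to 18 out of the matching. Averaging the pair titled 5 ended the calcium channels and the neuronal transcription factors.

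**Figure D3:**
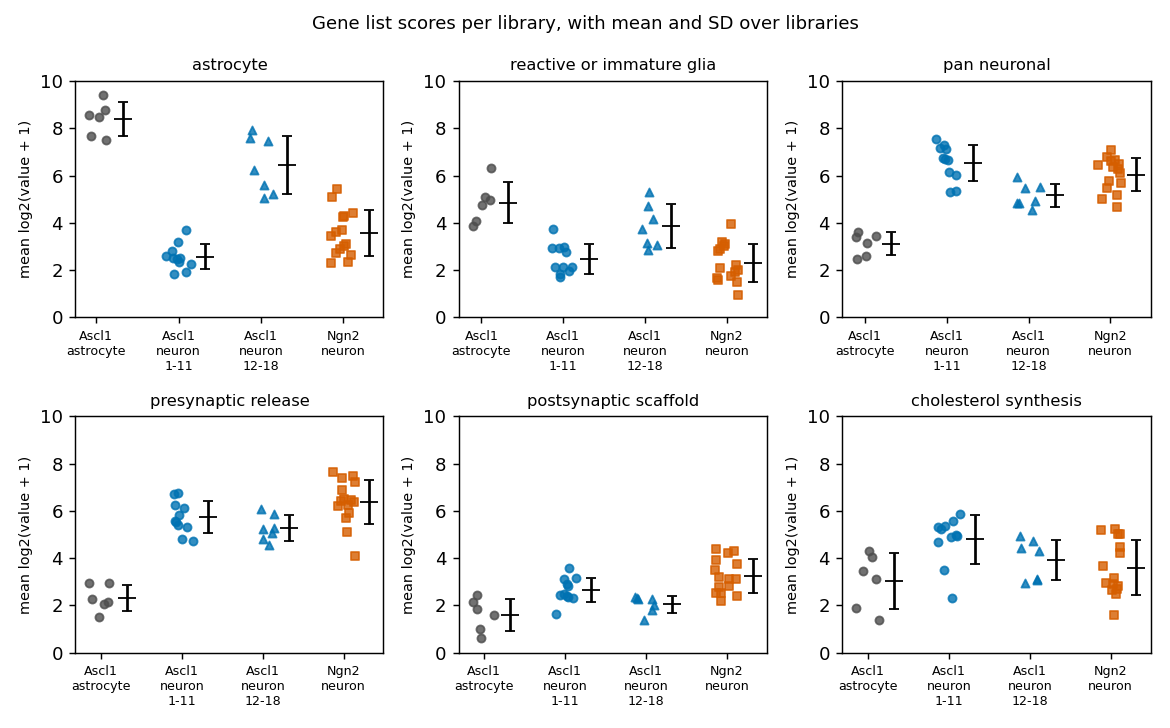
Score of 6 gene lists, the mean of log2(value + 1) over members, 1 point per library, with the mean and SD over libraries at the right of each group. The astrocyte score of the libraries labelled Ascl1 neuron 12 to 18 (5.07 to 7.93) lay above that of Ascl1 neuron 1 to 11 (1.85 to 3.72).

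The comparison of Ngn2 neurons with Ascl1 neurons set the 2 factor labels against each other. It did not separate the factors, since 7 of the 18 Ascl1 neurons held Neurog2 at 213 ± 145 and Ascl1 at 35.8 ± 41.6, so each log2 difference of a gene in this and the next 3 paragraphs was followed by its value without these 7. Cbln4 stood at 714 ± 512 normalised reads in the Ngn2 neurons (SD, n = 15) against 51.0 ± 86.2 in the Ascl1 neurons (SD, n = 18), a log2 difference of 5.66 and 6.47. Angpt1, an angiopoietin (ENSMUSG00000022309, chromosome 15, 42424723 to 42676977), stood at 184 ± 165 against 8.56 ± 18.9 (5.48 and 6.02). The synaptic vesicle gene Synpr stood at 398 ± 392 against 47.1 ± 137 (4.19 and 5.92), a mean of 15.5 without Ascl1 neuron 17. On the lower side, Nbl1, a BMP antagonist, stood at 36.4 ± 75.7 (20.6 without Ngn2 neuron 9) against 359 ± 285 (-4.56 and -5.71). Dll3 (ENSMUSG00000003436, chromosome 7, 28293553 to 28302238) stood at 53.9 ± 104 (31.3 without Ngn2 neuron 9) against 458 ± 793 (-3.56 and -5.76), a mean of 282 without Ascl1 neuron 2. The phosphatase Dusp6 stood at 34.6 ± 66.6 (23.0 without Ngn2 neuron 8) against 248 ± 227 (-3.87 and -4.86).

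The other genes named by size on the higher side were Braf (4.60 and 4.15), Igfbpl1 (4.54 and 4.67), Neurog2 (4.38 and 7.16), Plcxd3 (4.23 and 6.40), Cadm3 (3.82 and 4.58), Usp29 (3.75 and 3.23), Mdn1 (3.72 and 3.43), Sdc3 (3.56 and 5.31) and Ank3 (3.55 and 2.46), the last an organiser of the axon initial segment. On the lower side they were Ascl1 (-5.97 and -7.95), Resp18 (-4.44 and -5.41), Aldh18a1 (-3.96 and -3.42), Tubb6 (-3.93 and -5.66), Kcnip3 (-3.75 and -5.48), Cadm1 (-3.48 and -4.79), Msantd4 (-3.37 and -3.06), Fam110a (-3.31 and -5.24) and Sod3 (-3.29 and -2.53).

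The pan-neuronal list did not lie apart (median 0.14, with scores of 6.04 ± 0.713 against 6.01 ± 0.957), and 11 others did. Its score was 6.55 ± 0.765 in Ascl1 neuron 1 to 11 and 5.16 ± 0.498 in numbers 12 to 18, and its median was -0.20 without the latter and -0.02 without Ngn2 neuron 7, apart in neither. Cholesterol synthesis had a median of -0.90, with 17 of 19 members lower in the Ngn2 neurons, among them Sqle (-2.05 and -2.90), Dhcr24 (-1.71 and -0.87) and Hmgcs1 (-1.67 and -2.13), and a score of 3.61 ± 1.17 against 4.46 ± 1.03; the median was -0.96 without Ascl1 neuron 12 to 18. Neuronal transcription factors had a median of 0.79, with 19 of 22 higher, among them Zeb1 (2.28 and 0.79) and St18 (1.66 and 2.40), and 0.63 without those 7 libraries. Postsynaptic scaffolds had a median of 0.70 (0.81 without them), with 14 of 20 higher, among them the synaptic adhesion gene Lrrtm2 (3.19 and 3.89) and Nlgn2 (2.79 and 3.66). The genes associated with Neurog2 had a median of 0.56 (0.73 without them), with 13 of 16 higher, led by Trnp1 (2.20 and 2.90) and Neurod4 (1.96 and 2.52). Those associated with Ascl1 did not lie apart. Their median was 0.19, higher in the Ngn2 neurons, but -0.12 with rescaling to one total and -0.32 without those 7 libraries. Neuropeptides had a median of -0.26 (-0.23 without them), with 8 of 12 lower, led by Gal (-3.04 and -5.05) and Penk (-2.37 and -4.03). Here and in the next paragraph the counts of higher members include Ngn2 neuron 7 and are not given without it. Among genes matched on expression to the lists apart with more members higher, 51.2% to 59.2% were higher.

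The other 6 lists did not stay apart in the same direction without Ascl1 neuron 12 to 18. The astrocyte list had a median of -0.87 in the Ngn2 neurons, with 21 of 26 members lower, and 0.84 without these 7 libraries, apart on the other side; without Ascl1 neuron 12 alone it was -0.56. Reactive or immature glia, with 15 of 21 lower, had a median of -0.59 and 0.14 without the 7 (-0.39 without Ngn2 neuron 14 alone), and the glial potassium and gap junction channels, with 6 of 7 lower, had 0.12 without the 7 in place of -0.56. Presynaptic release had a median of 0.85, with 21 of 26 higher, among them Sv2b (3.75 and 4.12), Sv2c (2.66 and 2.94) and Bsn (2.44 and 3.39), and 0.34 without the 7. Potassium channels had a median of 0.48, with 15 of 22 higher, among them Kcnb2 (3.75 and 4.37) and Kcnq2 (3.12 and 3.84), and 0.30 without the 7. Immediate early genes had a median of -0.19, with 12 of 21 lower, and 0.00 without the 7.

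The postsynaptic list was ended by leaving out Ngn2 neuron 5 (0.60), 8 (0.64), 11 (0.63) or 13 (0.59), the genes associated with Neurog2 by leaving out Ngn2 neuron 2 (0.46) or 12 (0.38), and the neuropeptides by leaving out Ascl1 neuron 2 (-0.11). The potassium channels were ended by any 1 of 17 libraries (0.13 to 0.45): Ngn2 neuron 2, 3, 4, 6 or 7, or Ascl1 neuron 2, 3, 4, 7, 8 or 12 to 18. The immediate early genes were ended by any 1 of 24 (-0.20 to -0.07): Ngn2 neuron 1 to 6, 8, 9 or 12 to 14, or Ascl1 neuron 2, 4, 5, 7, 8, 9 or 12 to 18, and had -0.32 without Ngn2 neuron 7. Cholesterol synthesis stayed apart under each other setting run for lists and each left-out library. No list was recomputed at equal reads per library, so a share of depth in its difference was not tested. The neuronal transcription factors stayed apart except with linear means, and the postsynaptic list was also ended by upper-quartile scaling. With medians over cells 4 of the 11 stayed apart: presynaptic release, postsynaptic scaffolds, neuronal transcription factors and cholesterol synthesis. Receptors for glutamate, not among the 11, came to lie apart with medians over cells, a pseudocount of 0.1 and rescaling to one total. They also did so with the limit to members above 0 in at least 3 libraries. Linear means ended the genes associated with Neurog2, and the limit to members above 0 in at least 3 libraries ended the neuropeptides. The potassium channels were ended by either other pseudocount, rescaling to one total and linear means. The immediate early genes were ended by a pseudocount of 0.1, rescaling to one total, upper-quartile scaling, averaging the pair titled 5 and the limit to members above 0 in at least 3 libraries.

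**Figure D4:**
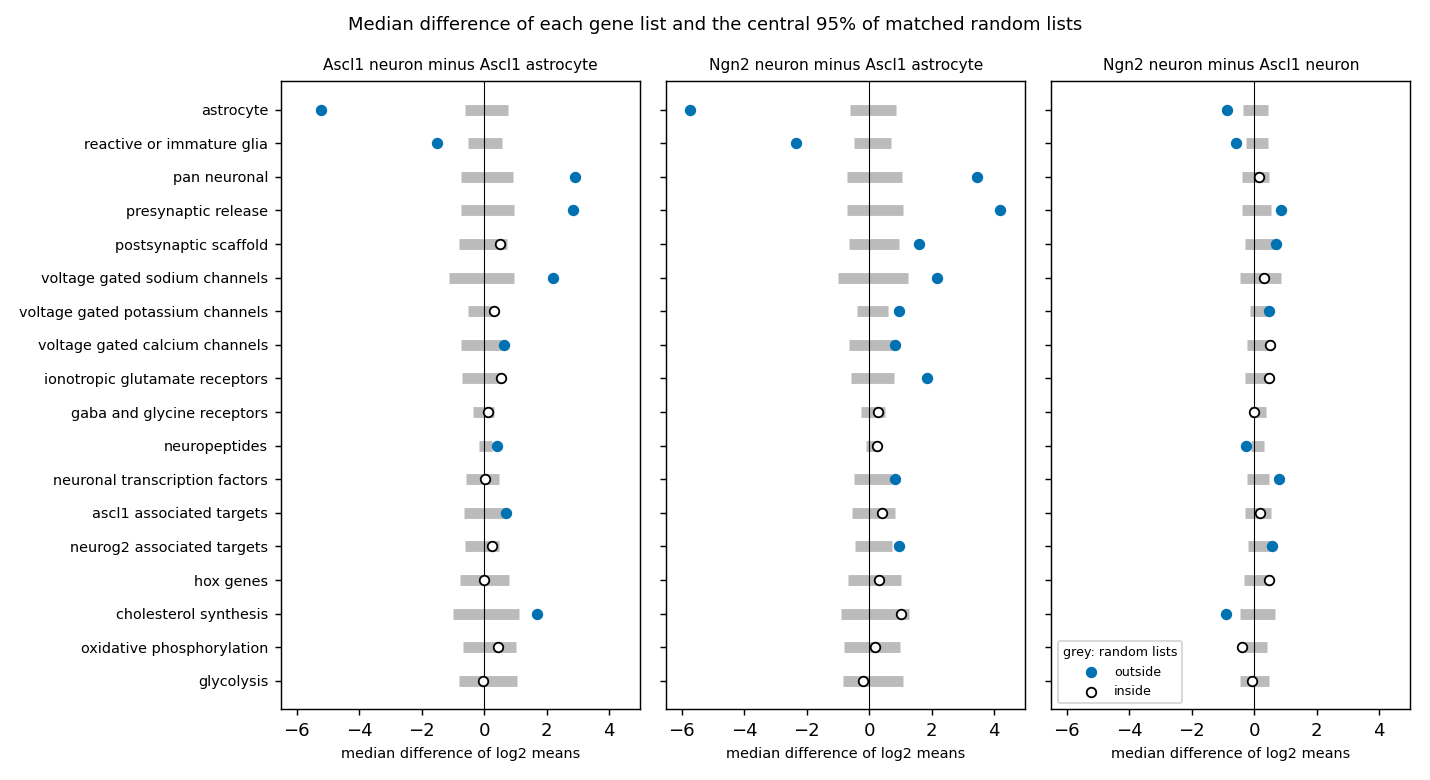
Median log2 difference of 18 gene lists in the 3 comparisons (points) and the central 95% of 10000 matched random lists (grey bars), with filled points for lists outside it. In the third panel the astrocyte list stood at -0.87, and at 0.84 without the libraries labelled Ascl1 neuron 12 to 18, which also turned reactive glia to 0.14.

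Transmitter genes were counted per library to ask which kinds of neuron were present. Gad1, which encodes a GABA-synthesising enzyme (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014), stood at 151 ± 221 normalised reads in the Ngn2 neurons (SD, n = 15), 71.2 ± 225 in the Ascl1 neurons (SD, n = 18) and 0.918 in the Ascl1 astrocytes (0.581 without number 3), 4 of 6 of which were above 0. The Ascl1 neurons had a median of 0.473, and a mean of 18.8 ± 33.9 (SD, n = 17) without Ascl1 neuron 11, which held 962. The log2 differences of Gad1 were 1.57, 3.49 and 1.92 in the 3 comparisons, and the first turned to -0.21 with medians over cells. Gad2, the other such enzyme, stood at 31.7 ± 65.3, 32.2 ± 84.1 and 0.684 ± 1.12, with log2 differences of 0.93, 1.52 and 0.60; the last was -0.33 without Ascl1 neuron 12 to 18, all 7 of which were at 0. Its mean was 16.5 without Ascl1 neuron 7, 19.1 without Ngn2 neuron 3 and 0.301 without Ascl1 astrocyte 3. At least 1 of the inhibitory genes Gad1, Gad2, Slc32a1 and Slc6a5 was above 0 in 13 of 15 Ngn2 neurons (86.7%, 95% interval 59.5 to 98.3), 13 of 18 Ascl1 neurons (72.2%, 46.5 to 90.3) and 4 of 6 astrocytes (66.7%, 22.3 to 95.7). The shares above 0 in the astrocytes set the background, and median genes above 0 were 7411.5, 8359 and 8372 in astrocytes, Ascl1 neurons and Ngn2 neurons. At 10 normalised reads or more the counts were 10 of 15 (66.7%, 38.4 to 88.2), 10 of 18 (55.6%, 30.8 to 78.5) and 0 of 6, which allows a share of up to 50%. The intervals of the neuron groups overlapped at both thresholds.

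A vesicular glutamate transporter gene (Slc17a6, Slc17a7 or Slc17a8) was above 0 in 2 of 15 Ngn2 neurons (13.3%, 1.66 to 40.5), 1 of 18 Ascl1 neurons (5.56%, 0.141 to 27.3) and 0 of 6 astrocytes, and reached 10 normalised reads in none of the 39 libraries. Without Ngn2 neuron 7 the first count was 1 of 14 (7.14%, 0.181 to 33.9), and the 1 Ascl1 neuron was number 13, so that 0 of 11 in numbers 1 to 11 held such a gene. Slc17a7 was at 0 in all libraries. Slc32a1, Slc6a5 and Chat, which mark GABA or glycine loading, glycine uptake and acetylcholine synthesis, were above 0 only in Ngn2 neuron 7. Th, the rate-limiting enzyme of catecholamine synthesis, was above 0 in 2 of 15 Ngn2 neurons (1 of 14 without number 7), in 5 of 18 Ascl1 neurons and in 1 of 6 astrocytes. Its mean was 0.099 ± 0.221 in Ascl1 neuron 1 to 11, with 2 above 0, and 29.4 ± 39.1 in numbers 12 to 18, with 3 of 7 above 0 (18.4 without number 15).

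**Figure D5:**
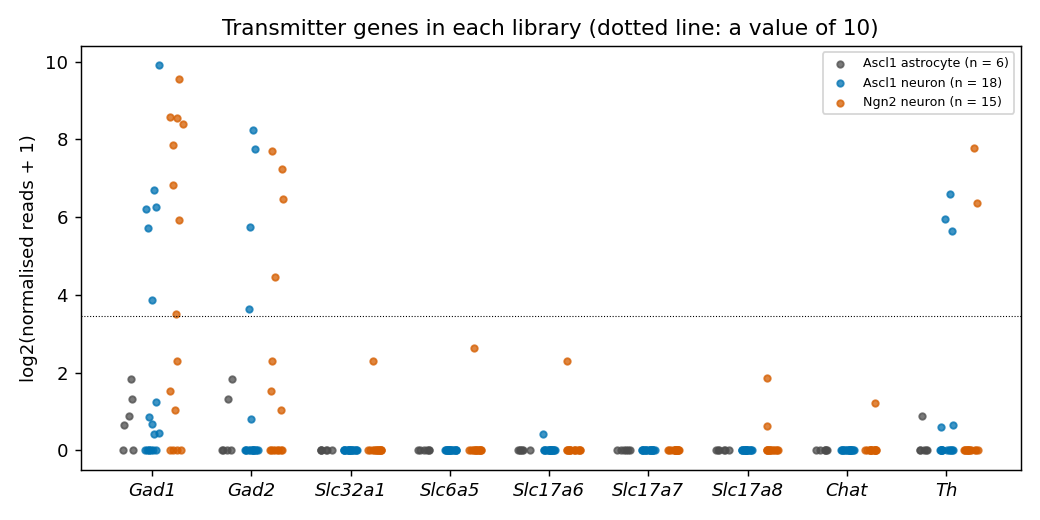
The 9 transmitter genes in each library, as log2(normalised reads + 1), 1 point per library and coloured by label. Gad1 and Gad2 passed a value of 10 (dotted line) in neurons of both factors and in 0 of 6 astrocytes, and the vesicular glutamate transporter genes passed it in none of the 39 libraries.

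Across the comparisons 18 lists lay apart in none. Their median log2 differences are given in the order Ascl1 neurons against astrocytes, Ngn2 neurons against astrocytes, and Ngn2 against Ascl1 neurons. Receptors for GABA and glycine had 0.12, 0.29 and 0.01, inhibitory identity 0.00, 0.17 and 0.15, excitatory identity 0.00, 0.08 and 0.08, and monoaminergic identity 0.10, 0.15 and 0.00. Ventral interneuron factors had 0.00, 0.15 and 0.12, Hox genes 0.00, 0.33 and 0.47, forebrain and midbrain factors 0.00, 0.08 and 0.08, and the cell cycle 0.00, 0.12 and 0.12. Heat shock genes had 0.44, 0.64 and -0.10, oxidative stress genes -0.56, -0.52 and -0.18, mitochondrially encoded genes -0.23, -0.69 and -0.15, glycolysis -0.04, -0.21 and -0.08, and oxidative phosphorylation 0.44, 0.20 and -0.38. Among markers of other cells, the oligodendrocyte lineage had 0.00, 0.12 and 0.12, microglia 0.00, 0.12 and 0.08, endothelium 0.00, 0.12 and 0.12, mural cells and fibroblasts 0.00, 0.08 and 0.04, and ependyma -0.15, -0.13 and -0.15. Chat, with 1 read (1.32 normalised) in Ngn2 neuron 7 alone, had a mean log2(value + 1) of 0.08 over the 15 Ngn2 neurons. Slc32a1, at 3.95 in that library alone, had 0.15. Medians of 0.08 to 0.15 in the comparisons with Ngn2 neurons can therefore rest on a few reads of that library. Without Ngn2 neuron 7, in the third comparison, inhibitory identity (0.56), the oligodendrocyte lineage (-0.31), mural cells (-0.42) and ependyma (-0.37) came to lie apart. So did mural cells in the other comparisons (-0.69 and -1.48), the ventral interneuron factors in the first (0.56) and the glial potassium and gap junction channels in the second (-1.31). The limit to members above 0 in at least 3 libraries set ventral interneuron factors apart in the first comparison and inhibitory identity in the second. It did the same for mural cells in both of these and for ependyma in the third. Without Ascl1 neuron 12 to 18, in the first comparison, oxidative stress genes (-1.60) and potassium channels (0.48) came to lie apart. The oxidative stress genes turned instead to 0.145 when Ascl1 astrocyte 5 of library 9864 alone was left out. Heat shock genes came to lie apart in the second comparison with a pseudocount of 10 or medians over cells. Oxidative phosphorylation did so in the third with a pseudocount of 10 or linear means. Rescaling to one total set oxidative stress genes apart in the first and ependyma in the third. Linear means set oxidative stress genes apart in the third and receptors for GABA and glycine in the first.

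Several of these 18 lists had no settled sign. In the third comparison without Ngn2 neuron 7, receptors for GABA and glycine turned to -0.06, monoaminergic identity to -0.21, forebrain and midbrain factors to -0.05 (-0.02 in the second comparison), the cell cycle to -0.02, microglia to -0.07 and endothelium to -0.08. Without Ascl1 neuron 12 to 18 oxidative stress genes turned to 0.29, mitochondrially encoded genes to 0.11 and ependyma to 0.06. Rescaling to one total turned glycolysis to 0.89 and 0.09 in the comparisons with astrocytes, and linear means turned Hox genes to -0.08 and oxidative phosphorylation to -0.32 in the second.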

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

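In groups of 4 to 10 libraries, which here meant the 6 Ascl1 astrocytes, the highest or lowest library was compared with the rest by its gap over the group's range. Of 43 measures, 3 passed, and chance passes about 1 in 20. Ascl1 astrocyte 5 of library 9864 had 12207 genes above 0, where the other 5 had 6061 to 8062. The same library had a Schwann cell score of 0.929, where the others had 0.00 to 0.211. Ascl1 astrocyte 4 had an endothelial score of 0.211, where the others were at 0. Any value above 0 would have passed here, and 1 read in this library was worth 2.72 normalised reads. No explanation was tested for these values.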

How the results depend on the processing

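The alternatives without Ngn2 neuron 7, without Ascl1 neuron 12 to 18, with 600000 reads per library and with upper-quartile scaling were chosen after seeing the data. Of 8036 alternative values, 118 had the other sign, 114 of them of lists not apart or of genes not named by size, such as Neurog2, Gad1, Gad2 and Th between some groups. None of the 72 results for genes named by size changed sign. The naming rule fixed this for single left-out libraries, and the choice of the largest differences favoured it elsewhere. Among the 33 lists apart, 4 values did, all without Ascl1 neuron 12 to 18 and between Ngn2 and Ascl1 neurons: astrocyte list 0.84, reactive glia 0.14, glial channels 0.12 and immediate early genes 0.004; the cause was not tested here. Of the values other than these 4, 7754 stayed within a limit and 278 did not, and the other 114 changes of sign are among them. The limit was the SD over cells, but for the 264 shares their 95% interval and for the 6 gene choices 16 of 24 genes kept. This SD was wide beside many differences. Without Ascl1 neuron 12 to 18, Neurog2 in the first comparison went from 1.95 to -0.84 and counted as within. The count of 7754 is therefore not a measure of stability. Rescaling to one total moved the median of 5000 genes by 0.70, 0.29 and -0.43 in the 3 comparisons, upper-quartile scaling by 0.38, 0.17 and -0.22, linear means by -0.51, -0.31 and 0.15, medians over cells by 0.23, 0.22 and 0.04, and a pseudocount of 10 by -0.15, -0.16 and 0.01; list percentiles are relative to matched genes.

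Sizes depended on the pseudocount and the mean. For Ascl1 neurons against astrocytes, presynaptic release had 4.35 with a pseudocount of 0.1, 1.50 with 10, 3.71 with linear means and 4.21 with medians, and the astrocyte list -3.30 with linear means. For Ngn2 neurons against astrocytes, the pan-neuronal list had 4.17, 2.33, 4.91 and 4.51, presynaptic release 5.70 (0.1), 2.52 (10) and 5.45 (medians), the astrocyte list -4.50 (10), Neurog2 4.13 (10) and Ascl1 -5.40 (linear). Between neurons, excitatory identity had 0.53 over members above 0 in at least 3 libraries. Inhibitory genes reached 10 in 0.0% of astrocytes. The share with a glutamate transporter was 0.0% in Ascl1 neurons at 1 or 10 and without 12 to 18 (0.0 to 5.88% leaving out each library), and 0.0% in Ngn2 neurons at 10. Median genes detected were 4553.5 in astrocytes at 10, and 7127 (at 1), 5523.5 (at 10) and 7340 (600000 reads) in Ascl1 neurons. Of 24 named genes, 18, 20 and 9 were shared with the choice from a smaller set of highly expressed genes. The minimum of 2000 genes removed no library. No paired analysis was possible because the labels pair no cells.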

Other observations

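Hox genes, which carry position along the body axis, were read in all groups: the score over 25 genes was 3.30 ± 0.541 (SD, n = 6) in the Ascl1 astrocytes, 3.01 ± 0.791 (SD, n = 18) in the Ascl1 neurons and 3.41 ± 0.777 (SD, n = 15) in the Ngn2 neurons. Single genes of lists that did not lie apart differed between neurons and astrocytes. In Ascl1 neurons against astrocytes the neuronal enolase Eno2 had a log2 difference of 5.37, the chaperone Hspa5 3.36, the stress response factor Nfe2l2 -5.60, the peroxidase Prdx6 -5.45 and the ciliary factor Foxj1 -5.47. In Ascl1 neuron 1 to 11 galanin, Gal, stood at 12139 ± 14910 (SD, n = 11), and in numbers 12 to 18 at 69.6 ± 54.5 (SD, n = 7).

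All 3 patterns weighed below were seen before their tests were chosen; the expected outcome was written after the result for the tests of endogenous Neurog2, depth, DNA, a wrong label alone as the source of astrocyte transcripts, and library runs.

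Neurog2 was high in the 7 libraries labelled Ascl1 neuron 12 to 18. For read exchange, they held 56.9% as many Neurog2 reads as the 15 Ngn2 neurons (3549 against 6237), over the 10% bound of the test. That bound was written after high Neurog2 had been seen in these libraries. It alone decided because 0 other genes qualified, so the ratio mostly restates the pattern. No conclusion on read exchange is drawn from it. Endogenous Neurog2 in proportion to Ascl1 is argued against, since the highest value in Ascl1 neuron 1 to 11 was 1.3 and the lowest in numbers 12 to 18 was 82.4. A wrong label cannot be told apart. Over 200 genes the 7 libraries lay a median 64.4% of the way from Ascl1 neuron 1 to 11 to the Ngn2 neurons, but the astrocytes themselves lay at 77.3%. Over the 68 genes where astrocytes lie nearer Ascl1 neuron 1 to 11 the 7 lay at 47.3% (38.2 to 54.9). The astrocytes lay at 3.19% over these genes, which were chosen for that nearness. Introduction of both factors into these cells was not tested and stays open.

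Ngn2 neuron 7 had 25472 genes above 0. Depth is argued against, since thinned to 600000 reads it held 21288 genes and the others 5205 to 10712. RNA of other cells in the culture is argued against, since 913 genes of smell and vomeronasal receptors were above 0, against 0 to 19 in the other libraries. The table held 966 such genes but leaves out most genes at 0 in every library. Hence 913 of 966 is not a share of all such genes. DNA carried into the library is a candidate explanation: over 7242 protein-coding genes at 0 in the other libraries or without an entry in the table, which 3533 were and which counted as 0, reads rose with exon length (Spearman rho 0.48 over genes, which are not independent, and 0.385 over the 3661 with a read), and 56.4% of 1335 receptor genes (53.7 to 59.1) held a read against 49.2% of 5907 others. Reads of RNA can also rise with length, so the rho alone cannot tell DNA from RNA. The DNA test replaced a first version that proved void, and no biological explanation was tested.

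Astrocyte transcripts were high in the 7 libraries labelled Ascl1 neuron 12 to 18. A wrong label alone is argued against, since 5 of the 7 lay above the highest Ngn2 neuron in the astrocyte score. RNA of astrocytes added in 1 share may account for them. Over 35 abundant astrocyte genes the log2 ratio to the astrocytes had an interquartile range of 1.44, within the 1.33 to 2.55 of single astrocyte libraries. Averaging 7 libraries narrows it, so this range alone cannot decide. The median gene stood at 15.4% of the astrocyte level (quartiles 7.93% and 21.5%), Apoe at 27.3% and Gfap at 12.1%. Single genes ran from Igfbpl1 at 0.878% and Neat1 at 1.34% to Pla2g7 at 53.5%. Of the 26 genes of the astrocyte list, 2 stand in another list and 16 had a mean of at least 10 in Ascl1 neuron 1 to 11, and the MACS sort selected astrocytes at the start and so would not remove them. A difference between library runs cannot be told apart, since 0 other groups had libraries in the second run, and incomplete conversion of these cells was not tested and stays open.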
